A study of Homo sapiens with 4 samples.

How the data were processed

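Total RNA of MDA-MB-231 cells was taken 48 hours after delivery of the construct and made into stranded total RNA libraries with a low-input kit, per the labels' protocols. The labels name 4 samples, 2 with SNRPA1 and 2 with mCherry. Reads were aligned to hg38 with STAR 2.7, per the submitters' processing notes. Exon inclusion was estimated with MISO, per the file headers, as a fraction from 0 to 1 (PSI, the posterior mean share of transcripts with the middle exon) with a credible interval. The MISO version, the level of that interval, the read-length setting, the event annotation and whether replicates were pooled are not given in the sources used here. The deposited tables also hold, for each event, read numbers that fit only the inclusion form, only the skipping form, both, or neither. The authors' deposited comparison table gives a Bayes factor, the ratio of evidence for a difference in PSI to evidence for none, and a PSI difference. That difference was SNRPA1 minus mCherry for all 40417 events, as checked against both tables.

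PSI from MISO uses reads inside the exon as well as junction reads, in proportion to length, so it can move where the density of reads in the exon moves against that in its neighbours. Where skipping reads are few, PSI rests on that density, and uneven coverage along a transcript enters the value. A low-input library amplifies few molecules, and reads are not independent molecules, so counting intervals are too narrow by an unknown amount. Summed over events, inclusion, skipping and shared reads were 15224395 in the SNRPA1 table and 12949185 in the mCherry table, and 59.6% and 62.4% of all reads at the events fitted neither form. A read at several overlapping events is counted in each.

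Tables were joined by event. The middle exon was matched to GENCODE 29 on hg38, and 97.1% of measured exons matched an annotated exon exactly. Of the measured exons, 3 had no gene and 446 overlapped more than 1 gene, for which the protein-coding gene with the most transcripts was named. Coordinates are counted from 1. A distinct exon was measured with at least 20 inclusion plus skipping reads in each table, and where an exon had several events the one with the most such reads was kept, which gave 14105 exons from 15641 events. An exon was called changed at a Bayes factor of at least 10 and a PSI difference of at least 0.2. Inclusion and skipping reads were also compared by a two-sided Fisher exact test per exon with Benjamini-Hochberg adjustment at 0.05. Shares have exact Clopper-Pearson 95% intervals.

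Gene lists, tests, filters and the rule for named genes were fixed before the data were examined. That rule took SNRPA1 and PLEC always, then the 12 exons called higher and the 12 called lower with the widest gap between credible intervals, 1 per gene, and in each list up to 4 called exons with the widest gap. Results of 1 splicing list and of some exons that the rule selects are not reported here. For 12 splicing lists the share of called exons was compared with that of other exons by a Fisher exact test, adjusted over the lists, and the median PSI difference was placed among 10000 random lists matched on deciles of read number, which is not reported because the median was 0 in every list. For 5 abundance lists the gene's event with the most reads was used, and the log2 ratio was taken after scaling each table to its total, with 0.5 reads added. Exon features were compared by permutation of the difference in medians with 100000 resamples, two-sided, or by Fisher exact test, and adjusted over 18 comparisons. The number of skipping reads implied by a PSI was the inclusion reads times (1 - PSI)/PSI, scaled by the length of a junction window over exon plus window. The window had a median of 56.9 nt (quartiles 42.2 and 89.2) over 66 exon values with both kinds of read, and exons not called held fewer skipping reads than implied as well. Intron sequence features and splice-site scores were not analysed here, because only annotation and transcript sequences were used.

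The read test was tested on simulated reads of 14105 exons, in which 200 exons were changed. It recovered 35.0% of the 100 exons with an odds ratio of 4.48 and 87.0% of the 100 with an odds ratio of 20.1, with 0 false calls among 122. The simulated reads were independent, without amplified copies or differences between cultures, so the false calls in these data can be more. Changes were placed only in exons with an appreciable share of both kinds of read, so the recovery does not cover exons with few skipping reads. Alternatives covered the PSI and Bayes factor thresholds, the read minimum, every event instead of distinct exons, credible intervals, the Fisher exact test, thinning of the deeper table, other scalings of the target gene, sums over exons for abundance, overlapping exons counted once in the lists, and a matched set for exon features. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.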

Results

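RNA sequencing was used to compare MDA-MB-231 cells, a human triple-negative breast cancer line, that carried a lentiviral SNRPA1 construct with cells that carried an mCherry construct, a red fluorescent protein used as the control. SNRPA1 encodes a protein of the U2 small nuclear ribonucleoprotein, which binds the branch site of introns. The labels list 2 replicates for each construct and RNA extraction after 48 hours. The deposited values are 1 table of skipped-exon events per construct and 1 table that compares them, so no value has a spread between replicates, and every difference given here lacks a replicate check. Summed over events, the SNRPA1 table held 4566291 reads that fit only inclusion or only skipping of a middle exon, and the mCherry table held 3802927. A further 10658104 and 9146258 reads fit both forms. A read that fits several overlapping events is counted in each. Inclusion is given as PSI, the share of transcripts that contain the exon, with the deposited credible interval. Of 40417 events in both tables, 14105 distinct exons in 6080 genes had at least 20 inclusion or skipping reads in each table, with a median of 94 reads in SNRPA1 and 79 in mCherry.

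The over-expressed gene was far more abundant in the SNRPA1 table. The 4 SNRPA1 events, on chromosome 15 of hg38, held 35449 of 15219096 event reads in the SNRPA1 table and 1419 of 12935062 in the mCherry table. These are 0.233% (exact 95% interval 0.231 to 0.235) and 0.011% (0.0104 to 0.0116), a ratio of 21.2 (20.1 to 22.4). Among 6115 genes with at least 200 reads SNRPA1 had the highest ratio, with a log2 value of 4.37, and CDK7, a kinase of the transcription machinery, came next at 1.37. The coding exon of SNRPA1 at 101286214 to 101286293 was included almost fully in both tables, with a PSI of 1.0 (0.99 to 1.0) in SNRPA1 and 0.97 (0.94 to 0.99) in mCherry. The other measured SNRPA1 exon, at 101287656 to 101287702, had a PSI of 0.26 (0.24 to 0.29) against 0.30 (0.19 to 0.44), and neither exon was called changed. Reads of the construct and of the endogenous gene were not told apart, so the PSI values with SNRPA1 do not describe splicing of the endogenous gene. The intervals of the read shares and their ratio cover counting error only, since the labels mention no molecular identifiers. They also treat a read counted in several events as separate reads, so they are too narrow.

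The question of which exons differ in inclusion with excess SNRPA1 was addressed first for PLEC, the gene of the cytoskeletal linker plectin. The 3381-nt coding exon of PLEC, on the minus strand of chromosome 8 at 143922504 to 143925884, encodes most of the rod domain. Its PSI was 0.96 (0.95 to 0.97) in SNRPA1 and 0.44 (0.43 to 0.45) in mCherry. Inclusion reads of this exon numbered 58185 against 19590, a ratio of 2.97, while reads that fit both forms numbered 128466 against 95601, a ratio of 1.34. Skipping reads were few. They made up 20 of 58205 in SNRPA1 (0.0344%, exact 95% interval 0.021 to 0.0531) and 0 of 19590 in mCherry, so the share of inclusion reads alone did not rise. For the 0 reads a one-sided limit of 3 counts gives a share of up to 0.0153%, which is not the same kind of limit as the exact interval. A two-sided Fisher exact test of these inclusion and skipping reads gave an adjusted p of 0.208. The 36-nt and 15-nt PLEC exons at 143937749 to 143937784 and 143938401 to 143938415 were skipped in both tables, with a PSI of 0 in each, and 1181 and 764 skipping reads in SNRPA1 against 785 and 526 in mCherry.

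Across the transcriptome, inclusion was called changed for 287 exons in 265 genes, 159 higher and 128 lower in SNRPA1. The higher share was 55.4% (exact 95% interval 49.5 to 61.2), an interval that includes equal numbers in both directions. It was 57.4% (50.6 to 64.0) at a Bayes factor of 20, 60.6% (52.0 to 68.7) at 100 and 59.5% (51.1 to 67.4) with a minimum of 50 reads, which exclude equal numbers, and 45.9% (36.9 to 55.2) with at least 5 skipping reads. Calls required a Bayes factor of at least 10 in the authors' deposited table and a PSI difference of at least 0.2. Of the 287 exons, 242 were coding, 17 lay in a 5′ UTR and 5 in a 3′ UTR, and the median PSI difference was 0.31 in size. Of the 287, 24 passed the Fisher exact test at an adjusted p of 0.05, all of them among the 122 with at least 5 skipping reads in a table, of which 56 were higher and 66 lower. The other 165 had under 5 in each table, and 114 of them had none at all, for which that test cannot pass.

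**Figure D1:**
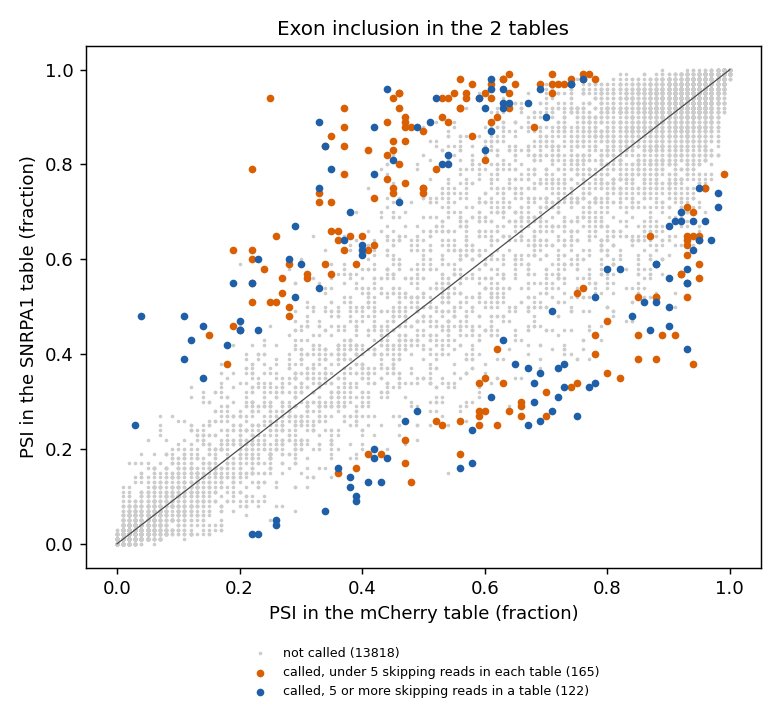
PSI of 14105 exons in the mCherry table (x axis, fraction) and the SNRPA1 table (y axis, fraction). Grey points are the 13818 exons not called, orange points the 165 called exons with under 5 skipping reads in each table and blue points the 122 others, and the line marks equal PSI.

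The widest gaps between credible intervals among exons with higher inclusion were in ERRFI1, PLEC, CD44, RAP1GDS1, MGME1, RCAN3, DPH7, RAD51AP1, NFIC, NCOA5, MPRIP and SON. ERRFI1 encodes a feedback inhibitor of the EGF receptor, and its coding exon on chromosome 1 at 8015308 to 8015384 had a PSI of 0.94 (0.86 to 0.99) against 0.25 (0.20 to 0.31). CD44, the hyaluronan receptor, followed at 35214852 to 35214914 of chromosome 11 with 0.85 (0.79 to 0.91) against 0.45 (0.40 to 0.50). Inclusion reads of this CD44 exon numbered 836 against 403, but each table held only 2 skipping reads, so the share of inclusion reads hardly moved. RAD51AP1, which acts in homologous recombination, had a 51-nt coding exon on chromosome 12 at 4545782 to 4545832 with a PSI of 0.48 (0.31 to 0.64) against 0.04 (0.01 to 0.09). Its reads showed the same direction, with 25 inclusion and 9 skipping reads in SNRPA1 and 1 and 25 in mCherry (Fisher exact, adjusted p = 7.03e-05). DPH7, which acts in diphthamide synthesis, was the other of these 12 genes to pass that test, with a PSI of 0.89 against 0.33 at 137564893 to 137564958 of chromosome 9 and an adjusted p of 0.00311 (Fisher exact). The 5916-nt exon of SON, a nuclear speckle protein, had a PSI of 0.56 (0.53 to 0.59) against 0.31 (0.30 to 0.33) with 0 and 1 skipping reads. No skipping read was present in either table for ERRFI1, RAP1GDS1, NCOA5 or MPRIP. For MGME1, a mitochondrial exonuclease, PSI was 0.94 against 0.53, but both skipping reads lay in the SNRPA1 table.

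Exons with lower inclusion were led by CEP57L1, CBFB, DPH2, PMS2P1, EIF4A1, STYXL1, MRPS31P4, HSP90AA1, FOPNL, EPB41 and FAM111B. Neither table held a skipping read for the exons of CEP57L1, DPH2, MRPS31P4, FOPNL or FAM111B. EPB41, the membrane skeleton protein 4.1, fell to 0.55 (0.44 to 0.67) from 0.93 (0.83 to 0.99) at 29060422 to 29060484 of chromosome 1, with 22 skipping reads against 2 (Fisher exact, adjusted p = 0.00396). STYXL1, with 17 skipping reads against 4, did not pass (Fisher exact, adjusted p = 0.0593). CBFB, a subunit of core-binding factor, had a PSI of 0.45 (0.37 to 0.55) against 0.87 (0.76 to 0.96). For EIF4A1, a translation initiation helicase, PSI was 0.78 against 0.99, and for the chaperone HSP90AA1 it was 0.54 against 0.76, each without a skipping read. These 2 genes have processed copies elsewhere in the genome, and PMS2P1 and MRPS31P4 are pseudogenes, so their values are uncertain where reads are shared.

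**Figure D2:**
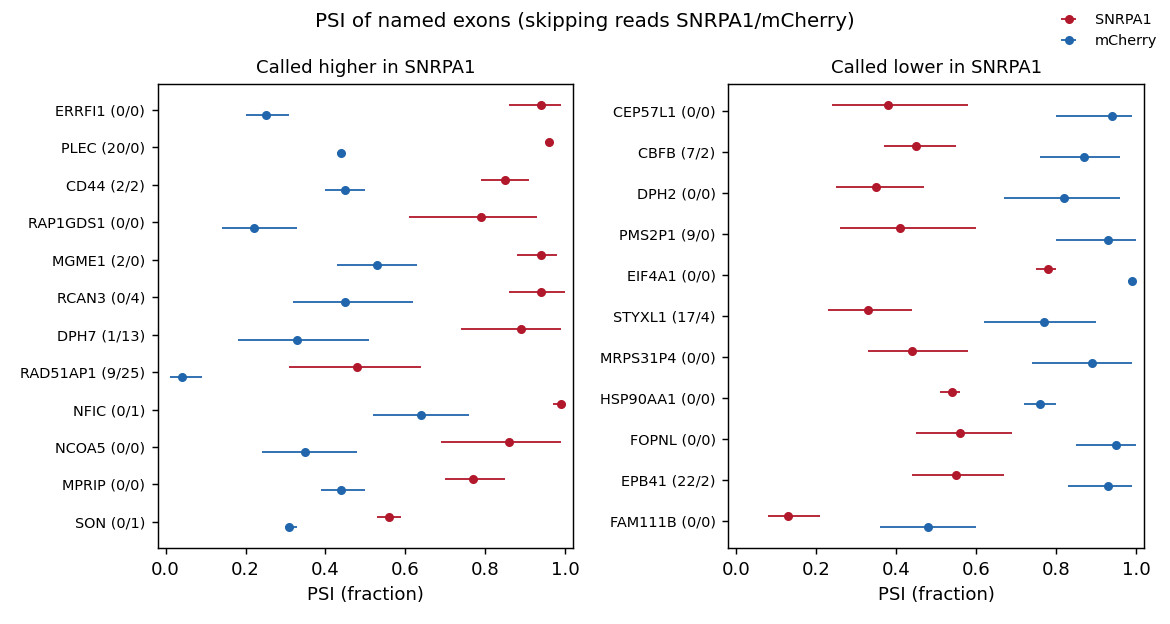
PSI (x axis, fraction) of called exons with the widest gap between intervals in each direction, with SNRPA1 in red and mCherry in blue, points for the posterior mean and bars for the deposited credible interval. Numbers after each gene are its skipping reads in SNRPA1 and mCherry, and RAD51AP1, at 9 and 25, has the most in the left panel.

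**Figure D3:**
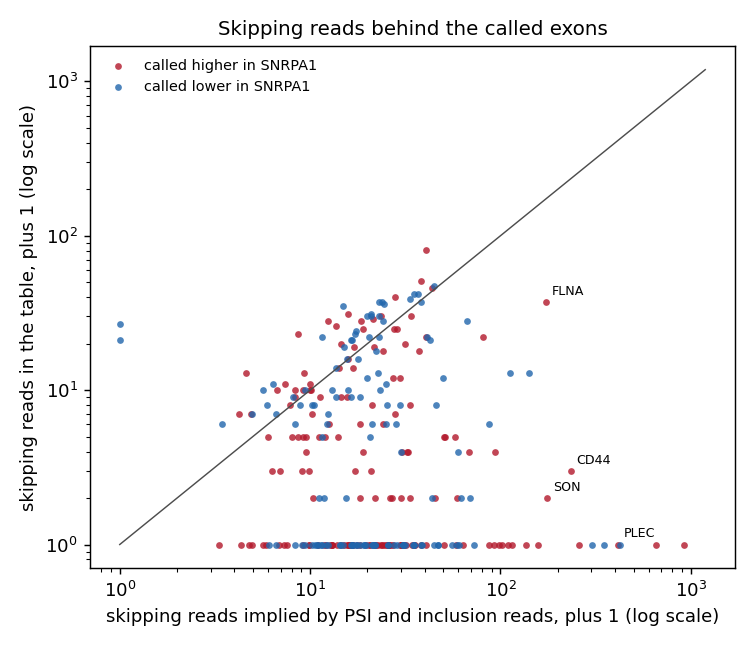
Skipping reads of the 287 called exons in the table with the lower PSI (y axis, reads plus 1, log scale) against the number implied by that PSI and the inclusion reads (x axis, reads plus 1, log scale), with a junction window of 56.9 nt. Red points were called higher and blue points lower in SNRPA1, the line marks equality, and PLEC lies at 0 reads where 413 were implied.

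Of 12 gene lists, chromatin regulators were the only one to pass the test for a larger share of called exons than among other genes. In that list 13 of 239 exons were called (5.44%, against 1.98% of other exons, odds ratio 2.85), with 7 higher and 6 lower in SNRPA1 (Fisher exact over exons, adjusted p = 0.0149). Members included MBD1, a reader of methylated DNA, at 0.84 against 0.37, the deacetylase HDAC7 at 0.33 against 0.74, and BRD9, a SWI/SNF subunit, at 0.07 against 0.34. The HDAC7 exon had no skipping read in either table. The MBD1 and BRD9 counts include 2 overlapping exons each. With overlapping exons of a gene counted once, 10 of 209 exons were called, 5 in each direction, and the list did not pass (Fisher exact, adjusted p = 0.114). Of the 13, 7 had under 5 skipping reads in each table, and the adjusted p was 0.26 with exons called by the read test and 0.408 with a minimum of 50 reads. Adjusted over the list alone, 6 of its exons passed the read test, 2 of them higher in SNRPA1, and 5 did over all exons. With overlapping exons counted once, 4 passed, 1 of them higher, and 3 did over all exons.

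Genes of adhesion and the cytoskeleton did not stand apart. In the actin cytoskeleton and adhesion list, 6 of 260 exons were called, 3 in each direction, among them PLEC, CD44 and EPB41. Of the lower calls 2 are overlapping exons of LIMCH1, named after its values were seen, which share 12 skipping reads against 3, so the list had 3 higher and 2 lower with overlaps counted once. FLNA, which encodes the actin crosslinker filamin A, had a 24-nt coding exon on the X chromosome at 154357251 to 154357274 with a PSI of 0.92 (0.89 to 0.94) against 0.63 (0.58 to 0.69). Its reads passed the Fisher exact test (adjusted p = 0.0471), with 947 inclusion and 33 skipping reads against 419 and 36. Skipping reads were thus similar in number, and inclusion reads made up 96.6% against 92.1%. The list for epithelial-mesenchymal splicing programmes holds genes, and had 3 calls in 146 exons. These are all measured exons of 38 genes, so a called exon need not be the one known from such a programme. The calls were CD44, MPRIP, a myosin phosphatase partner, at 0.77 against 0.44, and MAP3K7, the kinase TAK1, at 0.04 against 0.26. Adjusted over the list alone, 5 exons of each of these lists passed the read test, 1 and 0 of them higher in SNRPA1, against 4 and 3 over all exons. With overlapping exons counted once, 5 and 4 passed over the list alone, 1 and 0 of them higher. In both lists these include CD44 exons counted against the same 537 and 229 skipping reads, which counting overlaps once does not remove.

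Splicing factors did not differ detectably from other exons in the share called. The shares were 2.27%, 1.33% and 2.02% in the lists below, in that order, against 2.03% to 2.04% of other exons. U2 snRNP and branch-site factors had 1 call in 44 exons, SUGP2, at 0.56 against 0.27, and SR proteins and their kinases had 1 in 75, SON. The hnRNPs and other splicing regulators had 4 in 198, all higher: RBM39 at 0.98 against 0.63, TIAL1 at 0.25 against 0.03, HNRNPA3 at 0.97 against 0.65 and RBM34 at 0.83 against 0.45. Neither table held a skipping read for the exons of SUGP2, RBM39 or HNRNPA3. TIAL1, a relative of the U1-recruiting protein TIA1, passed the Fisher exact test with 20 inclusion and 33 skipping reads against 1 and 30 (adjusted p = 0.0391). Adjusted over the list alone, 2, 1 and 5 exons of these lists passed, against 0, 1 and 4 over all exons. Of the first 2, 1 is the over-expressed gene's own exon at 101286214, with 8 skipping reads against 4, whose reads may come from the construct. With overlapping exons counted once, the hnRNP list had 4, against 3 over all exons.

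Cell cycle, repair, death, traffic and decay genes did not differ detectably from the other exons either. Mitosis and cell cycle genes had 1 call in 149 exons, PCM1 at 0.58 against 0.80, and apoptosis genes 1 in 110, BCL2L12 at 0.64 against 0.95. DNA repair genes had 3 in 149, all higher and all with under 5 skipping reads, including the checkpoint kinase CHEK1 at 0.98 against 0.56. Endocytosis and vesicle traffic genes had 3 in 223, AP3M1 at 0.94 against 0.59, SEC24D at 0.59 against 0.88 and AP1B1 at 0.38 against 0.65. RNA decay and surveillance genes had 4 in 89, DIS3 at 0.51 against 0.88, SMG5 at 0.53 against 0.75, SMG1 at 0.35 against 0.14 and DCP1A at 0.89 against 0.44, and at a PSI difference of 0.1 this list had 8 and passed (Fisher exact, adjusted p = 0.0234). Adjusted over the list alone, 2, 2, 0, 5 and 1 exons of these 5 lists passed the read test, against 1, 2, 0, 2 and 1 over all exons. The first 2 are overlapping exons of CCNB1 and the next 2 of BIRC5. With overlapping exons counted once, the mitosis and apoptosis lists had 1 each. Apart from chromatin regulators, the adjusted p of a list was 0.647 or 1 (Fisher exact). The median PSI difference was 0 in each of the 12 lists, and since PSI is given to 2 decimals, ties at 0 keep this median from separating a list from others.

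Inclusion and skipping reads alone differed for 94 exons in 86 genes, 41 higher and 53 lower in SNRPA1 (two-sided Fisher exact, adjusted p of 0.05), and the PSI moved the same way in 93. The exons named here were chosen after their values were seen. NASP, a histone H1 chaperone, had the smallest adjusted p (4.94e-25, Fisher exact), with a 1017-nt coding exon on chromosome 1 at 45607321 to 45608337 whose PSI was 0.19 against 0.29. HNRNPA1, a splicing repressor, had 195 inclusion and 853 skipping reads against 276 and 609 for its 156-nt coding exon on chromosome 12 at 54283079 to 54283234 (Fisher exact, adjusted p = 7.66e-07). ECT2, which acts in cytokinesis, was higher, at 0.81 against 0.68 (Fisher exact, adjusted p = 1.15e-05), and the stress granule gene G3BP2 was lower, at 0.03 against 0.08 (Fisher exact, adjusted p = 5.14e-05). CD44 exons at 35198121 to 35198246 and 35211246 to 35211449 also passed, with 18.4% and 31.1% inclusion reads against 33.0% and 45.0%, but they were counted against the same 537 and 229 skipping reads. Their PSI was 0.04 against 0.05 and 0.06 against 0.05, so the second is the exon of the 94 whose PSI moved the other way, and its inclusion reads numbered 242 against 187. Other events of these exons, with other flanking exons, held 0 or 1 skipping reads in each table and showed no fall. PSI there was 0.08 against 0.07 for the first exon, and 0.09 against 0.08 and 0.98 against 0.96 for the second. The lower inclusion thus rests on the event that was kept. SMN1 and SMN2, near-identical copies, each had 210 skipping reads against 89 for their 54-nt exon, and these are uncertain because the copies share reads. Such tests compare 2 sets of reads, not the conditions. With the deeper table thinned to the depth of the other, 48 exons passed.

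Downstream introns were longer for exons called lower than for exons not called. The downstream intron had a median of 2885 nt for the 128 exons called lower and 1906 nt for the 13818 exons not called (permutation, adjusted p = 0.0198), and 2359 nt for the 159 called higher (permutation, adjusted p = 0.2). Exons called higher and lower, 526 nt apart, did not pass against each other (permutation, adjusted p = 0.66). With calls at a PSI difference of 0.1 the first difference was 492 nt and did not pass (permutation, adjusted p = 0.132). Against exons matched on reads and mCherry PSI it was 1024 nt and passed (permutation, adjusted p = 0.0146), although mCherry PSI still differed from that of the matched exons. GC content was 51.9% for exons called higher and 49.0% for exons not called (permutation, adjusted p = 0.0468), but against exons matched on reads and mCherry PSI the difference was 1.13 percentage points (permutation, adjusted p = 0.776). Exon length had a median of 135 nt for exons called higher, 127.5 nt for those called lower and 123 nt for the others. A length divisible by 3 was found for 52.2%, 49.2% and 42.6% of these exons. Upstream introns had medians of 1741, 1977 and 2110 nt. None of these 3 features passed in any pairing. PSI in mCherry, from which the calls are made, was 0.45 for exons called higher and 0.75 for those called lower, against 0.88 for the others, which differed from exons called higher (permutation, p = 1e-05, the smallest these resamples can give) but not past the threshold from those called lower (permutation, adjusted p = 0.059). Exons are not independent replicates, so these tests describe the 2 tables.

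Read numbers over the events gave a rough measure of abundance for 5 further gene lists. The unfolded protein response and stress list had a median log2 ratio of -0.23 over 19 genes, at the 0.43 percentile of 10000 random lists matched on read number. With reads summed over all exons its median was -0.162, at the 2.145 percentile, and that of epithelial markers was lower, at -0.217. Of its genes 17 had a ratio below 0, including the endoplasmic reticulum chaperone HSP90B1 at -0.33 and the disulfide isomerase PDIA3 at -0.41, and ASNS, asparagine synthetase, was at 0.28. Interferon-induced genes had a median of 0.06 over 39 genes, at the 95.5 percentile, with EIF2AK2 at 0.59 and DDX58 at -0.70, and the median was -0.01 with reads summed over all exons. Mesenchymal markers had a median of 0.04 over 16 genes, at the 78.1 percentile, with FN1 at 0.43 and ZEB1 at -0.01. The 9 epithelial markers had a median of -0.22, at the 18.1 percentile, with KRT8 at 0.12. Markers of blood, endothelial and nerve cells had 6 measured genes with at most 230 reads each in SNRPA1 and a median of -0.18, at the 56.3 percentile, which was 0.31 with reads summed over all exons. With 1 table per construct these percentiles carry no replicate error.

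**Figure D4:**
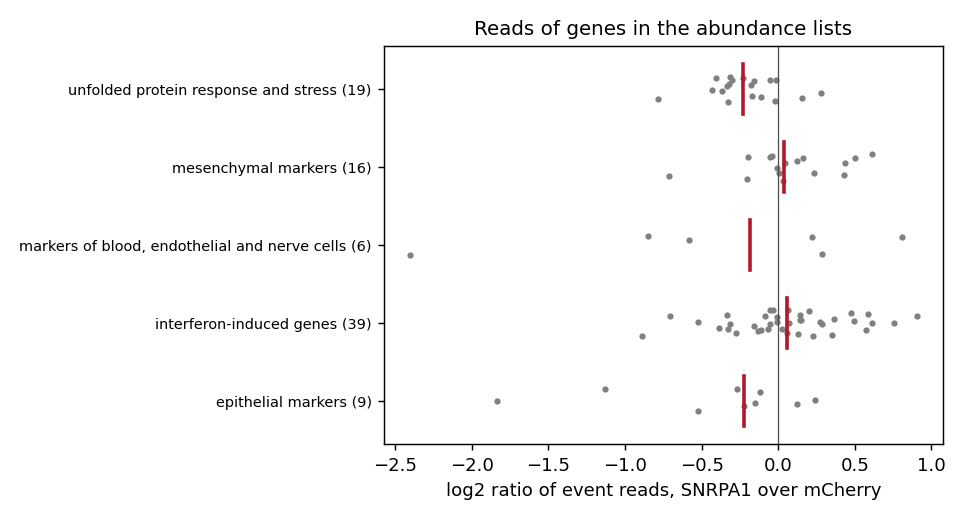
Log2 ratio of event reads, SNRPA1 over mCherry (x axis), for each measured gene of the 5 abundance lists, with the number of genes in parentheses. Grey points are genes and red bars list medians, of which the unfolded protein response list lies at -0.23, with 17 of 19 genes below 0.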

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

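The requirement of 5 skipping reads, the removal of ribosomal protein genes and pseudogenes, the counting of overlapping exons once, all alternatives of the read test and the inclusion reads of the target gene, were chosen after seeing the data. The 287 calls became 160 at a PSI difference of 0.3, 142 at a Bayes factor of 100, 148 at a minimum of 50 reads, 686 without a minimum, 24 with the Fisher exact test, 11 with the deeper table also thinned, and 122 with at least 5 skipping reads in a table. The other settings gave 223 to 403. The share of higher calls, 55.4%, was 47.4% without a minimum, 45.5% with thinning and 45.9% with at least 5 skipping reads, all with intervals that include equal numbers. It was 57.4% at a Bayes factor of 20, 60.6% at 100 and 59.5% at 50 reads, with intervals that exclude equal numbers (lower bounds 50.6, 52.0 and 51.1). The other settings gave 50.8% to 55.6% with intervals that include them. The 94 exons past the read test became 48 with thinning, and 82 with 1 exon per skipping junction, 36 higher and 46 lower in SNRPA1. The SNRPA1 ratio of 21.2 was 19.2 from inclusion reads of the event with the most reads.

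Chromatin regulators had 5 called exons with the Fisher exact test, 6 at 50 reads and 10 with overlapping exons counted once (Fisher exact, adjusted p = 0.114), and no longer stood apart in any of these. RNA decay genes had 8 at a PSI difference of 0.1 and then did (Fisher exact, adjusted p = 0.0234). With reads summed over exons, the median log2 ratio was -0.162 for the unfolded protein response list, at the 2.145 percentile instead of 0.43, -0.015 for interferon-induced genes and 0.307 for markers of blood, endothelial and nerve cells. At a PSI difference of 0.1, exons called higher were 18 nt longer than others and 8.62 percentage points more often divisible by 3, both now past the threshold, as was the mCherry PSI of exons called lower, at -0.195. The downstream intron difference of 492 nt and the GC difference of 2.39 points no longer were. Against matched exons the GC difference was 1.13 points and the downstream intron difference of exons called lower was 1024 nt, still past the threshold. The mCherry PSI of exons called lower was 0.19 higher, which follows from drawing the matched set to both directions at once. Elsewhere the cause was not tested. By raw share of inclusion reads PLEC moved by -0.000344 and MGME1 by -0.0073, opposite to their PSI. Over the 287 calls it moved with the PSI in 157 and against it in 16, and it cannot move in the 114 without a skipping read. Raw shares are not scaled to exon length, so their size cannot be compared with that of a PSI difference. With the Fisher exact test 39 named exons lost their call, 18 of which have no skipping read in either table and cannot pass.

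No paired analysis was possible because each construct has 1 table with no replicate numbers, and for the same reason none was left out in turn.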

Other observations

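Read numbers over the 12 splicing lists were not part of the planned comparisons. U2 snRNP and branch-site factors had a median log2 ratio of -0.14 over 18 genes, at the 3.18 percentile of matched random lists, although SNRPA1 itself stood at 4.37. U2AF2 was at -0.30, SF3B3 at -0.35 and SF3B1 at -0.10. SR proteins and their kinases had a median of -0.10 over 31 genes, at the 2.9 percentile, with SRSF3 at -0.39, SRSF2 at 0.25 and SRSF11 at 0.30. Mitosis and cell cycle genes had a median of 0.10 over 59 genes, at the 99.8 percentile, and chromatin regulators 0.06 over 87 genes, at the 99.2 percentile. These are values of 1 table per construct.

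Events listed for mCherry alone numbered 3365, and 1452 events were listed for SNRPA1 alone, although its table was deeper. Only 5 and 0 of these had 20 inclusion or skipping reads.

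The tests below of skipping reads, pseudogene copies and the direction of the read test were chosen after the result was seen, and those of transcript ends and GC content before. Most called exons had few skipping reads, 165 of 287 with under 5 in each table. If the lower PSI came from skipping, the table with the lower PSI should hold the skipping reads implied by its PSI and inclusion reads. It held 2126 where 8805 were implied, a ratio of 0.241, with a junction window of 42.2 nt taken from exons with both kinds of read, and 153 exons fell below their implied number (Poisson, 0.001), among them PLEC with 0 reads where 307 were implied and SON with 1 where 130 were. The same ratio was 0.378 over 2735 exons of middle PSI that were not called, of which 1038 fell below, so the implied number was not met there either, and the test cannot separate skipping from read density for the called exons as a set.

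The 165 exons with few skipping reads held 97 where 5990 were implied, a ratio of 0.0162, and the other 122 held 2029 where 2815 were, a ratio of 0.721. Exons of middle PSI that were not called, split the same way, gave 0.0165 and 1.05. Since the split is by skipping reads, these ratios alone do not test skipping. Of the 165, 133 fell below their own implied number (Poisson, 0.001), as did 904 of the 1702 exons of middle PSI not called with as few skipping reads, taken in the mCherry table. In those exons, called or not, the PSI was not matched by skipping reads of the event, and what set it was not tested. For the 165 exons, a flanking exon was an annotated transcript end in 35.8%, against 39.3% of exons not called with as few skipping reads (odds ratio 0.861, 95% interval 0.613 to 1.2, Fisher exact p = 0.377). Exons called higher and lower in this set differed in median GC by 1.75 percentage points (bootstrap interval -3.07 to 6.84, permutation p = 0.452). Ribosomal protein genes and pseudogenes held 6 of the 165 (odds ratio 2.19, 95% interval 0.78 to 4.99, Fisher exact p = 0.0662). Each interval includes no effect and an effect of the predicted kind, so transcript ends, GC-dependent coverage and shared reads stay open here, as does a change in inclusion with SNRPA1.

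A hypothesis that SNRPA1 mainly raises inclusion was tested on the exons past the read test. The share higher in SNRPA1 was 43.6% (exact 95% interval 33.4 to 54.2), which includes equal numbers in both directions and does not favour it. That interval treats the exons as independent, although some of them share skipping reads.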
